A study of Rattus norvegicus with 8 samples.

How the data were processed

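Total RNA of 8 whole newborn rat lungs was labelled with biotin and hybridised to 1-colour Affymetrix arrays, 1 array per lung, per the labels' protocols. The labels give the pups' age as day 0, and the growth protocol gives harvest on day of life 1, so the hour of harvest is not settled. Groups and replicate numbers, 4 arrays each, were taken from the sample titles. The deposited value table holds log2 expression values made by the authors with gene-level SST-RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each transcript cluster, which makes array distributions alike. The signal space transformation (SST) changes the scale of the signals beforehand, so folds depend on it. The version, library file and genome build are not given in the sources used here. Values ran from 2.57 to 19.93, and array medians are given with the results.

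The authors' deposited table of their own comparison gives log2 values of the same arrays and a signed fold score, the ratio of group means written as a negative reciprocal where it is below 1. Per its information sheet, the list came from significance analysis of microarrays in BRB array tools at a false discovery rate of 5% with 500 permutations, after a filter at percentile 50 of log-ratio variation. The sheet gives 2313 transcripts and the table holds 2312. Each log2 column was compared with each sample. All 8 columns matched the same-numbered sample of the other group by title. The sheet itself also carries 2 keys that number the groups in opposite ways. Titles were kept for the grouping, as fixed before the data were examined. The 8 linear copies of the log2 columns were not used.

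The value table has 70580 rows, of which 1738 are control rows and were left out of the tests. Among 68842 transcript clusters, the platform's annotation lists 1 gene symbol for 23446, several for 505 and none for 44891, and only those with 1 symbol were named. Of the named rows, 22077 carried a gene identifier found in the current RefSeq gene table. A gene with several rows (1182 genes) was represented by the row with the highest mean over all arrays, and genes with a mean below the percentile 30 of such means, a log2 level of 5.32, were left out. No coordinates are given, because the genome build behind the transcript clusters is not stated. One consequence of the row rule is that Uty entered the tests through a row outside the Y-linked cluster, so its Y-linked row is used only for the signal per array.

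The 15465 genes left were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), 4 arrays against 4 with no covariate, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p 0.05. Differences are on the deposited log2 scale, errors are the moderated standard errors, and folds are 2 to the size of that difference. For a named gene whose mean in a group lay below the level filter, the fold is a lower bound, with each signal below that level set to it. Gene lists were fixed before the data were examined: 59 lists of pathways, cell types and possible contaminating tissues, with 58 tested because 1 had fewer than 5 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 58 lists. The estimated correlation and fry, which asks whether a list's genes move on balance one way without setting them against other genes, were alternatives.

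The steps were tested on simulated data drawn from the means and residual spreads of the 15465 genes. With no simulated change 0 genes and 0 lists were called. Each gene was drawn independently of the others, so these 0 lists say nothing about lists whose genes move together. With only the neutrophil list shifted, 2 lists were called. With 200 genes changed, 10% of those changed 1.2-fold were recovered, 70% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 9 unchanged genes were called beside them. Differences under about 1.5-fold were therefore often missed in this simulation. The real fit called 3390 genes, and the Benjamini-Hochberg cut-off is less strict when more genes differ. The recovery rates thus need not hold for the real comparison.

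Genes named in the text follow a rule fixed before the data were examined. It takes the 15 genes with the largest difference in each direction among those that passed with groups that do not overlap, the 5 members with the smallest p of each list that passed and up to 2 of each other list, a fixed set of lung and vitamin D genes whatever their values, and genes with an array far from the others. Symbols that are only locus or clone numbers were passed over. The text names 77 of the genes so selected and tested.

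Alternatives fixed in advance were the level filter (none, or percentile 50), all rows per gene, all transcript clusters, quantile normalization, cyclic loess, median centring, the variance trend and prior, array weights, an ordinary 2-sample test, the replicate number as a block, the Y-linked level or the erythroid level as a covariate, each array left out in turn, and other thresholds. Leaving out the 2 arrays with high Y-linked signal, or the 2 with intermediate signal, was added after seeing the data, as were the comparison of list medians across divisions of the arrays and 1 list of amino acid response genes. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.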

Results

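RNA from whole lungs of 8 newborn rats was measured on Affymetrix rat transcript-cluster arrays, 1 array per lung. The titles name 4 lungs as control and 4 as from a vitamin D deficient mother. The control lungs are read here as offspring of dams fed an adequate diet (1000 IU of vitamin D per kg). The others are read as offspring of dams fed a diet with no added vitamin D (0 IU per kg). Both diets held 0.5% calcium and 0.4% phosphorus, and dams on the deficient diet were mated once serum 25-hydroxyvitamin D, the circulating form used to judge vitamin D status, was below 10 ng/ml. The comparison asks how the lung transcriptome at birth differs with the vitamin D status of the mother. The labels do not say whether pups of a group came from 1 litter or several, so the p-values measure the spread between these lungs, which can be smaller than that between litters. Median log2 signal per array lay between 5.499 and 5.647. The separation of positive from negative control rows, as an area under the curve, lay between 0.755 on titled deficient 4 and 0.795 on titled deficient 1.

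The grouping below is that of the sample titles, with control written as adequate, because the deposited sources disagree on which group is which. In the authors' deposited table all 8 columns hold the values of the same-numbered sample of the opposite group by title, to within 5e-05 on the log2 scale, while the smallest of the largest differences to the sample named alike was 6.61. Nothing in the files settles which naming is right. The groups are therefore written as titled adequate and titled deficient, every direction below is by title. The authors' deposited table runs the other way for each of its 2033 genes that were tested here, and it gives no direction for genes that it does not list.

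Genes higher in titled adequate included 14 of 16 neutrophil, 14 of 19 antimicrobial and acute phase, 19 of 21 immediate early, 19 of 28 inflammatory cytokine, 17 of 20 cholesterol synthesis, 15 of 20 ciliated cell, 12 of 22 surfactant and type 2 cell and 14 of 26 hypoxia response genes. All 8 lists passed with a preset correlation between genes, but with an estimated correlation only the antimicrobial and acute phase list did (adjusted p = 0.048, against 0.085 to 0.56 for the other 7). Genes higher in titled deficient differed by smaller factors, and few members of the lists that passed in that direction did so themselves. Of 15465 genes tested with limma, 3390 passed an adjusted p of 0.05, 2116 of them higher in the lungs titled adequate and 1274 higher in those titled deficient. At an unadjusted p under 0.05 there were 5789 genes. The difference was at least 2-fold for 269 genes higher in titled adequate and for 55 higher in titled deficient, and more than 4-fold for 60 and 0 genes. Over all genes tested, the 4 lungs of one group all lay above the 4 of the other for 4325 (28.0%), an arrangement that chance gives for 2.86% of genes, and 3116 of these passed. The count fell to 2178 without titled deficient 2, and the number of genes higher in titled deficient fell to 737 without that lung and to 810 without titled deficient 1.

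The balance of directions depended on how arrays were scaled. Of the genes called, 62.4% were higher in titled adequate with the values as deposited, 55.4% after cyclic loess, 46.4% after a second quantile normalization and 32.9% with each array centred on its median. Centring moved the median difference of all genes by 0.108 on the log2 scale, from 0.018 to -0.09. No gene called on the deposited values changed sign after loess or the second quantile normalization, and the medians of the 17 gene lists described below kept their sign under both. Centring moves all genes alike and by less than the smallest difference among the genes called, 0.163, so it could change no sign.

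Of the gene lists that passed, neutrophil genes had the largest median log2 difference, 1.857; Y-linked genes, described further on, had a larger one, 3.524, in a list of 5 members that did not pass (adjusted p = 0.24). Cd177, a surface glycoprotein of neutrophils, was 44.1-fold higher in titled adequate (log2 difference 5.46, SE 0.46, adjusted p = 0.000137), with a log2 signal of 13.26 ± 1.13 (SD, n = 4) against 7.80 ± 0.25 (SD, n = 4). S100a9 and S100a8, the subunits of calprotectin, were 22.5-fold (log2 difference 4.49, SE 0.21) and 13.1-fold higher (log2 difference 3.71, SE 0.18). The neutrophil collagenase gene Mmp8 was 13.9-fold higher and the neutrophil granule gene Olfm4 13.3-fold higher. Of 16 measured members of the neutrophil list, 14 were higher in titled adequate, 0 higher in titled deficient and 2 did not pass (15 higher when adjusted over the list alone). The adjusted p of the list was 1.3e-12 with camera at its preset correlation, and adjusted p = 0.085 with an estimated correlation. Of 19 antimicrobial and acute phase genes, 10 of which stand on other lists too, 14 were higher in titled adequate (15 adjusted over the list alone), with adjusted p = 9.7e-10 and, with an estimated correlation, adjusted p = 0.048. Orm1, an acute phase protein, was 15.9-fold higher. The stefin genes Stfa2l2 and Stfa2l3 read higher by log2 differences of 4.24 and 3.46, but they belong to a family of near-identical copies whose probes may not separate them. Erythroid genes, which mark red cells, did not move with the neutrophil list: their median log2 difference was 0.078 over 22 genes, and it turned to -0.03 with arrays centred on their medians.

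Immediate early genes, which are induced within minutes by many stimuli, were higher in titled adequate for 19 of 21 members (19 adjusted over the list alone). The nuclear receptor genes Nr4a1 and Nr4a2 were 21.0-fold (log2 difference 4.39, SE 0.21, adjusted p = 5.24e-06) and 8.38-fold higher, and Jun was 3.04-fold higher. The list had adjusted p = 2e-10, and adjusted p = 0.22 with an estimated correlation. Fos was 16.3-fold higher with a wide spread: log2 signals on titled adequate 1 to 4 were 9.08, 7.98, 13.23 and 12.44, against 6.40 to 7.14 on the lungs titled deficient. The log2 difference of Fos, 4.02, was 4.92 without titled adequate 2 and 3.17 without titled adequate 3, and Fos did not pass without titled adequate 4 (3.44, adjusted p = 0.0511) or without titled deficient 2 (3.98, adjusted p = 0.0516). Ccn1, a secreted matrix protein induced alongside these genes, was 11.9-fold higher.

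Inflammatory cytokine and NF-kappaB genes followed the same direction for 19 of 28 members, with 2 higher in titled deficient (21 and 2 adjusted over the list alone). The neutrophil-attracting chemokine gene Cxcl1 was 10.5-fold higher in titled adequate, Il1b, which encodes interleukin 1 beta, 8.15-fold higher and Ccl3 at least 14.1-fold higher. The value for Ccl3 is a bound, with each signal below the level filter, a log2 level of 5.32, set to that level, as on 3 of the 4 lungs titled deficient. Its log2 signals on titled adequate 1 to 4 were 7.68, 6.90, 11.43 and 10.81, and the bound was 8.43-fold without titled adequate 3 and 24.0-fold without titled adequate 2. Il1b had log2 signals of 7.72 and 7.49 on titled adequate 1 and 2 and of 10.01 and 9.37 on titled adequate 3 and 4. The list had adjusted p = 5.5e-06, and adjusted p = 0.56 with an estimated correlation. Of 26 macrophage and monocyte genes, 14 were higher in titled adequate and 2 in titled deficient (16 and 3 adjusted over the list alone). Among them the integrin gene Itgam, shared with neutrophils, was 3.70-fold higher, the scavenger receptor gene Cd163 1.95-fold higher and the complement gene C1qa 1.90-fold higher. The macrophage list had adjusted p = 4.3e-05, and adjusted p = 0.33 with an estimated correlation. Interferon response genes had 3 of 29 members higher in titled adequate (1 adjusted over the list alone), among them Stat2 at 1.85-fold and Ifit1 at 2.20-fold. Ifit1 did not pass without titled adequate 3 or 4 or without titled deficient 2, 3 or 4 (adjusted p = 0.0511 to 0.0709). Their list had adjusted p = 0.0089, and adjusted p = 0.74 with an estimated correlation, and it rested on titled adequate 3 and 4: without these arrays 1 member was higher and the list did not pass (adjusted p = 0.85), while without titled adequate 1 and 2 the number was 15 (adjusted p = 2.7e-08). Antigen presentation genes had 3 of 17 members higher (3 adjusted over the list alone), with adjusted p = 0.021 and, with an estimated correlation, adjusted p = 0.69. They too depended on titled adequate 3 and 4, with 1 member higher and no call without these arrays (adjusted p = 0.2) and 7 higher without titled adequate 1 and 2 (adjusted p = 0.0037).

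**Figure D1:**
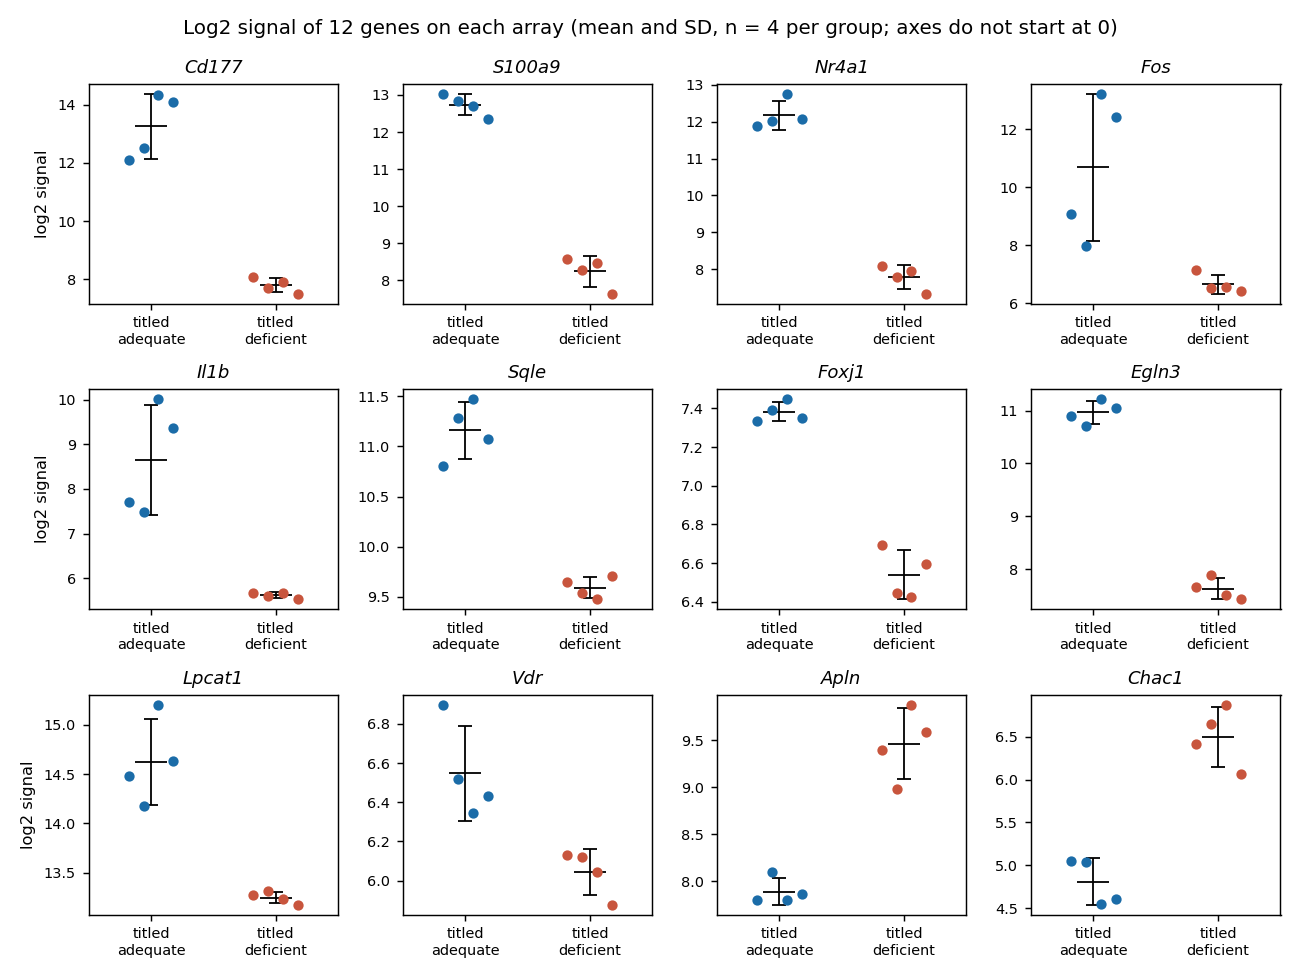
Log2 signal (vertical axes, which do not start at 0) of 12 genes on each array; points are lungs, the black bar is the group mean and the whiskers are the SD (n = 4 per group, by title). In each panel the 4 lungs of one group lie above the 4 of the other; Fos and Il1b spread widely among the lungs titled adequate, from 7.98 to 13.23 and from 7.49 to 10.01.

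Cholesterol synthesis genes were higher in titled adequate for 17 of 20 members and higher in titled deficient for 0 (18 and 0 adjusted over the list alone). Sqle, which encodes squalene epoxidase, was 2.96-fold higher (log2 difference 1.56, SE 0.14, adjusted p = 0.000205). Lss, which encodes lanosterol synthase, was 2.82-fold higher, Fdft1, which encodes squalene synthase, 2.74-fold higher and the sterol sensor gene Insig1 1.91-fold higher. Together the members had adjusted p = 7.4e-09, and adjusted p = 0.32 with an estimated correlation. Hypoxia response genes were higher in titled adequate for 14 of 26 members, and 12 did not pass (16 higher and 1 lower adjusted over the list alone). Egln3, an oxygen-dependent hydroxylase that is itself induced by hypoxia, was 10.1-fold higher (log2 difference 3.34, SE 0.14, adjusted p = 5.09e-06), Ndrg1 4.64-fold and the glucose transporter gene Slc2a1 2.03-fold higher. That list had adjusted p = 9.8e-06, and adjusted p = 0.15 with an estimated correlation.

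Of the lists of epithelial cells, those of ciliated and alveolar type 2 cells passed toward titled adequate with the preset correlation but not with an estimated one (adjusted p = 0.45 and 0.24), whereas the lists of type 1 cells (adjusted p = 0.56), club and goblet cells (adjusted p = 0.56) and basal and squamous epithelium (adjusted p = 0.24) did not pass. Ciliated cell genes passed for 15 of 20 members in that direction and for 0 in the other (18 and 0 adjusted over the list alone). Foxj1, the transcription factor of motile ciliogenesis, was 1.79-fold higher (log2 difference 0.84, SE 0.08, adjusted p = 0.00027), Hydin 2.25-fold and Tekt1 1.75-fold higher. This cilia list had adjusted p = 6.7e-07, and adjusted p = 0.45 with an estimated correlation. Without titled adequate 3 and 4, 6 members were higher in titled adequate, and the list still passed with the preset correlation (adjusted p = 2.3e-05). Of 22 surfactant and alveolar type 2 cell genes, 12 were higher in titled adequate and 1 in titled deficient (13 and 1 adjusted over the list alone). The phospholipid remodelling enzyme gene Lpcat1 was 2.60-fold higher, Napsa 2.00-fold, the transcription factor gene Nkx2-1 1.80-fold and the surfactant lipid transporter gene Abca3 1.55-fold higher. Among surfactant proteins, Sftpd was 1.61-fold (adjusted p = 0.00618) and Sftpb 1.30-fold higher (adjusted p = 0.00715). Sftpa1 did not pass (log2 difference 0.37, SE 0.12, adjusted p = 0.0538). Among the fits that left out 1 array, it passed only without titled adequate 1 (0.49, adjusted p = 0.0109). Sftpc read 19.87 ± 0.03 (SD, n = 4) and 19.86 ± 0.03 (SD, n = 4) near the highest value in the table, 19.93, where an array may no longer resolve a difference. Mean signals of Sftpb (19.02 against 18.64) and Sftpa1 (18.50 against 18.13) were also high, so their differences may be compressed. Whether they were was not tested. Surfactant genes as a list had adjusted p = 2.5e-05, and adjusted p = 0.24 with an estimated correlation. Hedgehog and FGF morphogenesis genes were higher for 10 of 30 members (13 higher and 1 lower adjusted over the list alone), with Foxa1 1.88-fold, Fgfr2 1.85-fold and Sox9 1.66-fold higher. Their list had adjusted p = 0.00018, and adjusted p = 0.32 with an estimated correlation.

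**Figure D2:**
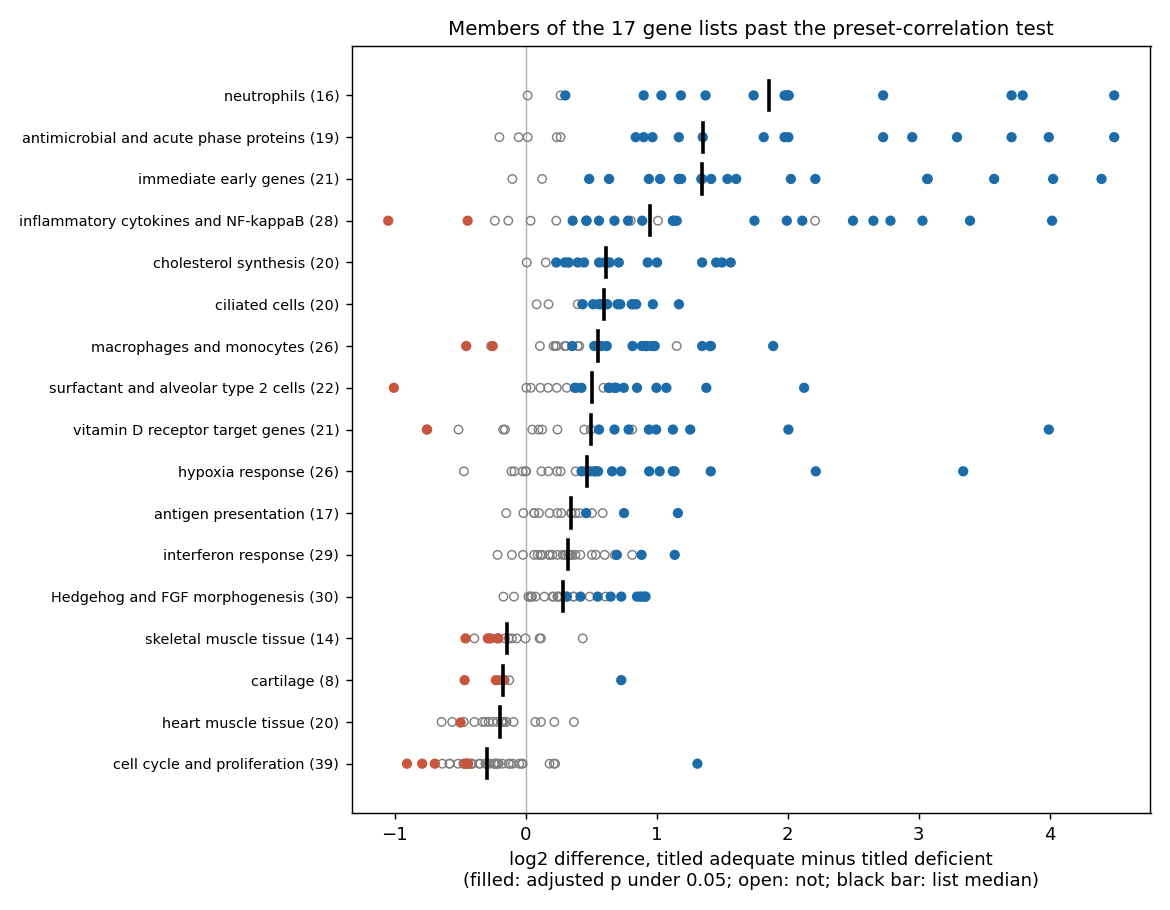
Log2 difference, titled adequate minus titled deficient (horizontal axis), of each measured member of the 17 gene lists past the test with a preset correlation; the number of members is in parentheses. Filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians, from 1.857 for neutrophils to -0.297 for cell cycle.

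Of 21 measured genes listed beforehand as vitamin D receptor targets, 9 were higher in titled adequate and 1 in titled deficient (10 and 2 adjusted over the list alone). Besides Orm1, the list members higher in titled adequate included the antimicrobial peptide gene Camp at 4.01-fold, Txnip at 2.39-fold and Klf4 at 1.92-fold. Whether these genes respond to vitamin D in the rat, in lung or in any other tissue, was not tested. Their values are therefore no evidence of receptor action. Orm1 and Camp also stand on the acute phase and antimicrobial list, Camp on the neutrophil list too, and Klf4 on the immediate early list. Of the 21 members, 12 are shared with other lists. The list had adjusted p = 0.015, and adjusted p = 0.22 with an estimated correlation. The receptor gene Vdr was 1.42-fold higher in titled adequate (log2 difference 0.51, SE 0.12, adjusted p = 0.0169), and its partner gene Rxra was 1.67-fold higher (adjusted p = 0.00663). Vdr read low, at 6.55 ± 0.24 (SD, n = 4) against 6.04 ± 0.12 (SD, n = 4). Both means lay below the median of the negative control rows, which was at least 6.825 on each array. The limit is not particular to Vdr: the titled deficient means of Camp (5.65) and Orm1 (5.55) lay below it too. Antigenomic background rows had lower means, 3.71 to 3.925 per array, and whether the negative control median marks a floor was not tested. Cyp2r1, a 25-hydroxylase gene, also read below that median in both groups (6.14 and 6.27). It did not pass (log2 difference -0.13, SE 0.08, adjusted p = 0.276). Cyp24a1, the catabolic enzyme gene usually induced by the hormone, Cyp27b1, Cyp27a1 and Gc lay below the level filter and were not tested: Cyp24a1 read 4.10 ± 0.02 (SD, n = 4) in titled adequate and 4.17 ± 0.05 (SD, n = 4) in titled deficient. The list of vitamin D metabolism and signalling genes had 4 of 13 members higher in titled adequate (4 adjusted over the list alone). It did not pass camera (adjusted p = 0.14, and adjusted p = 0.38 with an estimated correlation). It passed fry (adjusted p = 8e-04), which does not set a list against other genes and by which 26 of 58 lists passed.

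Genes higher in titled deficient differed by smaller factors. Abcb1b, a drug efflux transporter gene, was 3.58-fold higher there (log2 difference 1.84, SE 0.29, adjusted p = 0.00315) and Tnfrsf12a, a receptor of the tumour necrosis factor family, 3.46-fold higher. Chac1, which encodes a glutathione-degrading enzyme, was at least 2.27-fold higher (adjusted p = 0.000474), a bound set in the same way because its signals in titled adequate lay below the level filter, and the mitochondrial folate enzyme gene Mthfd2 3.05-fold higher (log2 difference 1.61, SE 0.12, adjusted p = 6.79e-05). The adaptor gene Bcar3 was 3.16-fold higher, the vasoactive peptide gene Apln 2.98-fold, the histone gene H2ac4 2.75-fold, Hivep2 2.67-fold, Ndnf 2.52-fold and the Notch ligand gene Dll1 2.43-fold higher. Histone genes have near-identical copies, so H2ac4 is uncertain. Of 39 cell cycle and proliferation genes, 6 were higher in titled deficient, 1 in titled adequate and 32 did not pass (6 and 1 adjusted over the list alone). Ccna2 and Ccne2, which encode cyclins, were 1.87-fold and 1.62-fold higher and the replication clamp gene Pcna 1.73-fold higher. Without titled deficient 2, Ccna2 and Pcna did not pass (adjusted p = 0.0513 and 0.0518). Mki67 did not pass (adjusted p = 0.222). The list had adjusted p = 0.00013, and adjusted p = 0.72 with an estimated correlation, and it rested on titled adequate 1 and 2: without these arrays 3 members were higher in titled deficient and the list did not pass (adjusted p = 0.29), while without titled adequate 3 and 4 the number was 22. Muscle and cartilage genes also passed toward titled deficient at small medians, but some members read near the level filter. Mean log2 signals, titled adequate against titled deficient, were 5.395 against 5.604 (Myh2), 5.209 against 5.498 (Mb) and 5.482 against 5.71 (Col9a3). Acta1 (8.147 against 8.606) and Matn4 (7.864 against 8.33) read higher. Over all transcript clusters, named or not, the median log2 difference, adequate minus deficient, was -0.077. Whether a shift of low signals accounts for the list medians was not tested. The median log2 difference, adequate minus deficient, was -0.144 for skeletal muscle (4 of 14 members higher in titled deficient, 6 adjusted over the list alone, list adjusted p = 0.021, and adjusted p = 0.32 with an estimated correlation). It was -0.2 for heart muscle (1 of 20, and 1 adjusted over the list alone, list adjusted p = 0.0042, and adjusted p = 0.67 with an estimated correlation) and -0.173 for cartilage (3 of 8 higher in titled deficient and 1, Sox9, in titled adequate, 6 and 1 adjusted over the list alone, list adjusted p = 0.034, and adjusted p = 0.49 with an estimated correlation). The cartilage list did not pass without titled adequate 1 and 2 (adjusted p = 0.062) or without titled adequate 3 and 4 (adjusted p = 0.11), and skeletal muscle did not pass without titled adequate 3 and 4 (adjusted p = 0.12).

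Vascular and matrix lists did not pass. Endothelial genes had 2 members higher in each group among 21 (2 and 2 adjusted over the list alone, list adjusted p = 0.95). Nos3, the endothelial nitric oxide synthase gene, was 1.54-fold higher in titled deficient (adjusted p = 0.0141), whereas the vascular growth factor gene Vegfa was 1.44-fold higher in titled adequate (adjusted p = 0.0372). Vegfa did not pass without titled adequate 1, 2 or 4 or without titled deficient 1, 2 or 3 (adjusted p = 0.0523 to 0.0868). The receptor genes of Vegfa, Kdr (log2 difference 0.18, SE 0.12, adjusted p = 0.328) and Flt1 (log2 difference -0.06, SE 0.10, adjusted p = 0.678), did not pass. Elastic fibre genes passed for 2 of 21 members (1 adjusted over the list alone, list adjusted p = 0.87), including Eln, the elastin gene, at 1.78-fold higher in titled adequate (log2 difference 0.83, SE 0.10, adjusted p = 0.0012). Collagen and fibrillar matrix genes passed for 2 members in titled adequate and 4 in titled deficient among 24 (2 and 4 adjusted over the list alone, list adjusted p = 0.24). Matrix protease and inhibitor genes were higher in titled adequate for 8 of 23 members and in titled deficient for 2 (9 and 3 adjusted over the list alone). Their list came near the threshold (adjusted p = 0.058, and adjusted p = 0.67 with an estimated correlation). By fry its adjusted p was 0.0074. Col1a1 (adjusted p = 0.567), Acta2 (adjusted p = 0.626) and Tgfb1 (adjusted p = 0.319) did not pass. The type 1 cell gene Ager was 1.34-fold higher in titled adequate (adjusted p = 0.0271) and did not pass without titled adequate 1 or 2 or titled deficient 1 or 2 (adjusted p = 0.0553 to 0.067). The list of type 1 cells did not pass (adjusted p = 0.56).

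In all, 17 of 58 gene lists passed camera with a preset correlation of 0.01, 13 toward titled adequate and 4 toward titled deficient. Only the antimicrobial and acute phase list passed with an estimated correlation. It shares S100a8, S100a9 and Camp, among others, with the neutrophil list, so it is not separate from that list. At least 17 lists passed in 8 of the 35 divisions of the 8 arrays into 4 and 4, the titled one included. The 7 others had 3 arrays of one titled group together, which keeps part of the difference between the groups, and the 18 divisions with 2 arrays of each group on a side reached at most 15. The absolute median difference of a list was largest in the titled division for 13 of the 17 lists, in a 2-sided exact permutation test whose smallest p is 0.0286 before any correction for the number of lists. It was as large or larger in 7 divisions for cell cycle, in 5 for interferon response, in 4 for heart muscle and in 2 for antigen presentation, the titled one included.

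Y-linked genes, which mark male tissue, were unevenly spread. Ddx3y had log2 signals of 13.45, 13.43, 8.71 and 7.40 on titled adequate 1 to 4 and of 5.71 to 5.90 on the lungs titled deficient. Eif2s3y and Kdm5d followed the same order of arrays, and all 3 passed (adjusted p = 0.0213, 0.0414 and 0.0413). The authors' deposited table lists Eif2s3y with signed folds of 30.4 and -1.62, so a further row, which did not represent the gene here, went the other way. Eif2s3y and Kdm5d did not pass without titled adequate 1 or 2 or any 1 lung titled deficient (adjusted p = 0.0776 to 0.0905), nor did Ddx3y without titled deficient 2 (adjusted p = 0.0511). The signal of 4 Y-linked genes on titled adequate 3 was 3.27% to 4.16% of that on titled adequate 1 and 2, above the level on the lungs titled deficient, and 1.01% to 1.43% on titled adequate 4. Male signal and the titled group therefore overlapped. Without titled adequate 1 and 2, an alternative chosen after seeing the data, 2674 genes passed, 2046 of them among the 3390 and in the same direction. There the counts higher in titled adequate were 13 of 16 for neutrophil genes, 19 of 21 for immediate early genes, 21 of 28 for cytokine genes, 14 of 20 for cholesterol synthesis, 16 of 20 for ciliated cells and 15 of 22 for surfactant genes. Without titled adequate 3 and 4 these counts were 14, 18, 14, 12, 6 and 12, and 2834 genes passed.

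**Figure D3:**
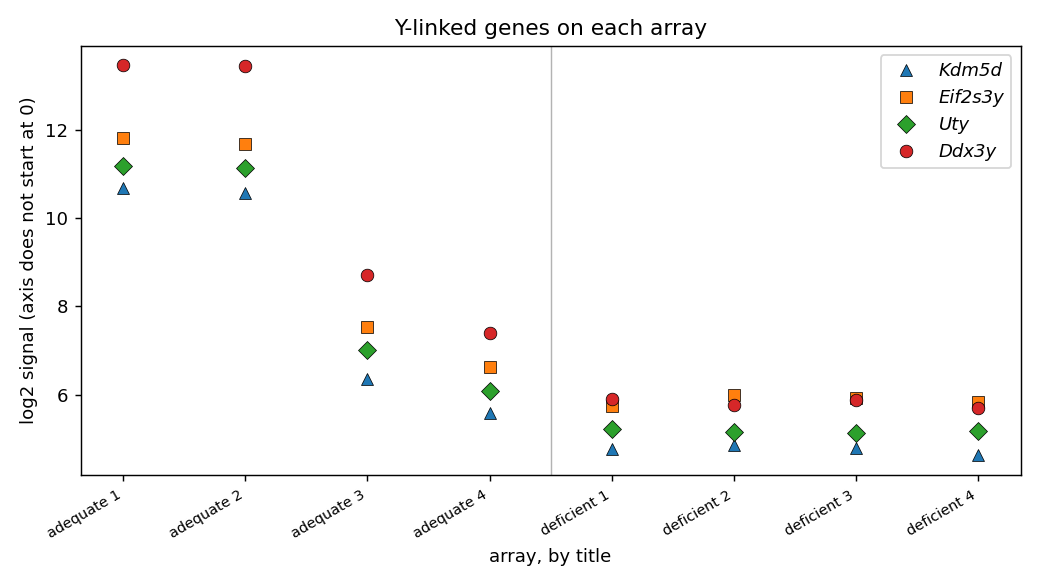
Log2 signal (vertical axis, which does not start at 0) of 4 Y-linked genes on each of the 8 arrays (horizontal axis, by title). Titled adequate 1 and 2 are highest, with Ddx3y at 13.45 and 13.43; titled adequate 3 and 4 lie between these and the 4 lungs titled deficient.

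The authors' deposited table lists 2312 transcript clusters selected from the same arrays, 1954 of them higher in the columns named deficient and 358 lower, so it is not independent evidence. Of these, 2033 were among the genes tested here, 1885 passed an adjusted p of 0.05, and all 2033 had the opposite sign by title. The Spearman correlation of log2 folds across these genes was -0.997, and genes are not independent replicates. A further 1505 genes passed here that the authors' deposited table does not list.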

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

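The tests of explanations in this part were chosen after the results had been seen; the rule for arrays that stand apart was fixed beforehand. The rule was applied to 172 sets of 4 arrays, 154 from named genes and 18 from array quality measures. In 4 sets an array had a gap to its neighbour that took up nearly the whole range of its group. Chance gives 1 in 20 for unselected, independent sets. Here 68 of the 77 named genes passed the test, which favours a small spread within groups, and the sets share the same arrays. The number of sets therefore says nothing about array quality. Titled deficient 4 was apart for Sox9 (7.98 against 8.21 to 8.23, gap over range 0.899) and for Txnip (15.90 against 15.34 to 15.42, 0.865). Titled deficient 2 was apart for Sftpb (18.67 against 18.63 to 18.64, 0.882) and titled adequate 1 for Col1a1 (14.30 against 14.87 to 14.99, 0.831).

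The number of genes that differed between the titled groups, 3390, was reached in 1 of the 35 divisions of the arrays, the titled one. The highest count in the other divisions was 0. A share of 1 in 35, 0.0286, is the smallest that the divisions allow. It argues against a chance division only if the lungs are independent, and their litters are not given. The other divisions mix the titled groups, so their counts of 0 say nothing more. The 17 gene lists are another matter: 8 of the 35 divisions gave at least as many, up to 22, so chance cannot be excluded for the number of lists. The 7 others had 3 arrays of one titled group together and so kept part of the difference between the groups, and the 18 divisions with 2 arrays of each on a side reached at most 15. Sex as the whole cause is argued against by the 2046 genes that were called the same way without titled adequate 1 and 2, although part of the list may still reflect it. Titled adequate 3 and 4, with intermediate Y-linked signal, stay in that fit. With the Y-linked level as a covariate, 1526 of the 3390 genes were called the same way. That level is partly confounded with the group, so how much of the loss is due to sex cannot be told. The lower quality of titled deficient 4 is argued against as the cause by 2721 genes called the same way without it. The mother's vitamin D status stays open beside litter and handling of each group, which the labels do not give and which were not tested.

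Titled adequate 3 and 4 had Y-linked signals between those of the other lungs titled adequate and those of the lungs titled deficient. Raised background on these arrays is argued against: the larger median rise of the 6 other Y-linked rows was 0.04 on the log2 scale, against at least 0.757 for each of the 4 genes. A small share of RNA from a male pup is a candidate explanation, since the 4 genes gave similar shares within an array, the highest over the lowest being at most 1.42. Whether such RNA came from another lung of this series or from elsewhere was not tested, and no biological explanation was tested.

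Neutrophil transcripts were higher in titled adequate by a median log2 difference of 1.857 (quartiles 1.001 and 2.186 over 16 genes). More blood left in those lungs is argued against by the erythroid genes, whose median was 0.078 (quartiles -0.019 and 0.216 over 22 genes). Over the 13 of these genes at least 1 log2 unit above the level filter it was 0.127, with an upper quartile of 0.368. More leukocytes of every type could be neither excluded nor shown. T, NK and B cell genes had a median of -0.063 over 13 genes, but only 6 of these lay at least 1 log2 unit above the level filter, and the 13 went both ways: 3 of 7 T and NK cell genes were higher in titled adequate and 2 of 6 B cell genes in titled deficient. A larger number of neutrophils, or more transcript per neutrophil, may each account for the values and were not told apart by any test here. The dam's vitamin D status, the time from birth to harvest and the litter stay open as untested.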

How the results depend on the processing

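Leaving out 2 arrays was an alternative chosen after seeing the data; the others were planned. Among the called genes that an alternative tested, which is 2607 of the 3390 at the percentile 50 filter and all of them elsewhere, 2 changed sign, both with the Y-linked covariate. Centring could change none. Of the values of the 77 named genes under the alternatives, 1738 kept their direction and side of the threshold, 78 lost the call, 7 gained one and 16 changed sign. Camera uses no robust prior and no ordinary test, so lists were not run under those 2 choices.

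The number of genes (3390) became 6332 over all transcript clusters, of which 37% were higher in titled adequate. With the Y-linked covariate, by which group and signal are partly confounded, it became 2206. Of these, 1526 were among the 3390 and in the same direction. The number became 1324 at unadjusted p under 0.05 with a fold of 1.5. Genes higher in titled adequate (2116) became 1401 with centred arrays and 956 at that fold. Genes higher in titled deficient (1274) became 3988 over all clusters, 2854 centred, 844 with the ordinary test, 709 with the covariate, 368 at that fold and 2005 at adjusted p under 0.1. Leaving out each array gave 2178 to 3134 genes, 1441 to 1945 and 737 to 1189 in the 2 directions. Lists (17) became 26 with no filter, 30 over all clusters, 1 with an estimated correlation and 26 with fry, and 13 to 20 without each array. The cause was not tested, except that fewer arrays give less power.

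With the replicate number as a block, 1758 genes passed, 1197 and 561 by direction. Same-numbered lungs did not deviate together (correlations of -0.171, 0.044, -0.353 and -0.28), and none correlated best with its own number, so the block pairs nothing.

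Sign changes all concern differences that did not pass under that alternative. With the Y-linked covariate, Eif2s3y turned to -0.119 and Kdm5d to -0.115 by construction, Cyp2r1 to 0.064, Sftpc to -0.031, Acta2 to 0.217, Tgfb1 to -0.358 and Mki67 to 0.033. Sftpc was -0.008 after quantile normalization, -0.103 centred, between -0.007 (without titled adequate 2 or titled deficient 3) and 0.014 without each array, and -0.019 without the high Y-linked arrays, where Acta2 was 0.094 and Tgfb1 -0.112. Without the intermediate arrays Flt1 was 0.034 and Col1a1 -0.013. The cause was not tested.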

Other observations

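Amino acid response genes formed a further group, tested after Chac1, Mthfd2 and 2 more members had been seen among the largest differences. On a list of genes regulated by ATF4, the transcription factor of the amino acid and integrated stress response, 31 members besides these were measured, 23 of which stand on no list fixed in advance. Of the 31, 14 were higher in titled deficient and 2 in titled adequate, with a median log2 difference of 0.251 toward titled deficient. The amino acid transporter gene Slc7a1 was 1.95-fold higher (adjusted p = 0.00108), Atf4 itself 1.77-fold higher (adjusted p = 0.00692) and the asparagine synthetase gene Asns 1.65-fold higher (adjusted p = 0.0151), while Psat1 was 1.89-fold higher in titled adequate (adjusted p = 0.00277); these were chosen after their values were seen. Camera gave p = 3.1e-06 with the preset correlation and p = 0.033 with an estimated correlation. Of the 23 members, 12 were higher in titled deficient and 2 in titled adequate, with a median of 0.405. Camera gave p = 3.3e-05 for them with the preset correlation and p = 0.061 with an estimated correlation, so whether ATF4 targets as a group were higher in titled deficient stays open.

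Several other lists did not pass camera but held genes past the threshold. Wnt signalling had 13 of 31 members higher in titled adequate and 1 in titled deficient (list adjusted p = 0.058). Lung liquid clearance and ion transport had 5 of 18 higher in titled adequate and 1 in titled deficient (list adjusted p = 0.083). The circadian clock list had 6 of 17 higher in titled adequate and 2 in titled deficient (list adjusted p = 0.46). By fry the Wnt, lung liquid and circadian lists had adjusted p = 0.0085, 0.0021 and 0.029. Of 39 mitochondrial respiratory chain genes, 0 passed, with a list adjusted p of 0.47 by camera and 0.82 by fry.

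The first principal component held 54.9% of the variance and separated the titled groups, from -28.5 to -21.2 in titled adequate and from 21.2 to 30.7 in titled deficient. The second held 17.5%, with titled adequate 1 and 2 at 22.1 and 17.9 and titled adequate 3 and 4 at -22.5 and -13.7. The third held 13.7%, with titled deficient 4 at -27.0.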
